A study of Mus musculus with 7 samples.

How the data were processed

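Total RNA from brown adipose tissue of 7 NOD/ShiLtJ mice was sequenced on an Illumina NovaSeq 6000 after isolation with a kit for lipid-rich tissue, per the labels' protocols. Reads were aligned with STAR 2.7.9a to the Ensembl release 101 primary assembly, per the labels' protocols. The submitters' processing notes also name featureCounts 2.0.3 of Subread, Salmon 1.5.2, edgeR and limma, with no role for each. The library kit, its strandedness and the counting options are not given in the sources used here. The authors deposited 1 table of expected counts per gene, not normalized, whose values have up to 2 decimals. Non-whole values can arise where reads are divided between genes, and genes holding them carried 43.5% to 54.8% of each library's counts. Reads of near-identical copies or of genes on opposite strands can be assigned in part to the wrong gene. Which genes share reads is not given, and genes that the naming rule below gives are called uncertain where they have non-whole counts or an overlapping gene.

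The table had 55774 lines, of which 287 repeated a gene identifier with identical values and were removed, leaving 55487 genes. Of these, 99.5% matched GENCODE release M21 on GRCm38 by identifier, from which coordinates, exon length, GC content and overlapping genes were taken. Groups came from the treatment label of each sample, and replicate numbers follow the order of the samples. The animal codes in the titles are not shared between groups, so no pairing was used, and they are the only sign that replicates are separate mice. The p-values measure the spread between these samples. No batch or age is given in the labels, and sex was read from Xist and 4 Y-linked genes.

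Expected counts were rounded to whole numbers, and genes were kept by edgeR's filterByExpr on the group. Libraries were scaled by TMM, with factors of 0.755 to 1.25, and tested with edgeR 4.0.16 (estimateDisp and glmQLFit, both robust, and glmQLFTest) on the group alone in R 4.3.3. P-values are two-sided and adjusted by Benjamini-Hochberg over 16823 genes with a threshold of 0.05. The SE of a log2 change was taken as its size over the square root of the F statistic. The coefficient of variation between replicates was 28.0%. CPM are normalized by the TMM-scaled totals, and log2 CPM used a prior count of 2. With 10815101 to 28528471 counts per library and 3 or 4 mice per group, precision is limited by the number of mice. On simulated data with the real means, dispersions and library sizes for this comparison (16823 genes, 200 changed), the test recovered 74% and 24% of genes lowered by 2 and 1 on the log2 scale, and 90% and 30% of genes raised by 2 and 1. It made 119 calls, of which 10 were false. The simulated genes were drawn independently, without correlation between genes or outlying libraries, so these rates may not carry over to the real data.

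Gene lists (36 lists, 708 genes) for the pathways and cell types of this tissue were written before the data were examined, as were the tests, the alternatives and the rule for naming genes. Of the 36, 35 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 35. The list of sex-linked genes served only to read the sex of the mice. Camera with an estimated correlation and fry (limma 3.58.1) were alternatives. Single values, and the mean log2 CPM of each list per library, were compared by exact two-sided permutation over the 35 splits of the 7 libraries. Libraries of a group were compared before averaging. Spearman correlations of log2 CPM were 0.951 to 0.974 within groups and 0.923 to 0.967 between them, and no pair matched within sampling noise (chi-square per degree of freedom of at least 30.9).

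Genes named are, first, Ucp1, Adipoq, Lep and Ins2 whatever their result. Next come the 12 protein-coding genes per direction with the largest fold change among those past the threshold, with a mean of at least 1 CPM and no overlap between the groups. Last, each list described gives up to 4 called members with the largest change, or up to 2 members with the smallest p. Some genes that this rule gives are not reported here, while all counts and list tests include them. Of 90 genes so named, 26 overlap another gene and 23 have non-whole counts. Other genes named in the closing section were chosen after their values were seen, except those of lists written before their test.

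Alternatives fixed beforehand were DESeq2 size factors and upper quartile scaling, no filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom with quality weights, each library left out, a threshold of 0.1, a test against a fold change of 1.5, protein-coding genes only, mitochondrially encoded genes left out, and a skeletal muscle score or sex as covariate. Chosen after seeing the data were a correction of each library for exon length and GC content by smooth terms (mgcv 1.9.3), an analysis of females only, and the omission of mitochondrial, 7SL and 7SK RNA. The list tests with sex as covariate were also added then. Where libraries or genes were left out, the filter on low counts was rerun, so the members tested in a list could change. No column of the table was left unused.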

Results

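RNA was measured by sequencing in brown adipose tissue, the heat-producing fat depot, of 7 NOD/ShiLtJ mice, a strain that develops autoimmune diabetes. The groups were CB-100 (4 mice) and sham, given KRBH buffer (3 mice). Mice with blood glucose of 190 to 230 mg/dL had CB-100 injected under the skin for 7 days, and the labels repeat this protocol for the sham samples without a schedule of their own. CB-100 is the part larger than 100 kDa of buffer conditioned by brown adipocytes, given at 1.5 mg per kg of body weight. Tissue was taken 2 to 8 weeks after injection, with no week given per mouse. The sample titles also carry a code, nd on each CB-100 sample and d on each sham sample, which the labels do not spell out. Whatever it marks cannot be separated from the injection. The series title names an effect of large proteins secreted by brown adipocytes on the brown fat of diabetic mice as its subject, and the comparison of CB-100 with sham addresses it.

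Library totals ran from 10815101 to 28528471 counts, the highest in CB-100 replicate 4. Counts of Xist and of Y-linked genes showed 1 male mouse in each group, CB-100 replicate 3 and sham replicate 3, and 5 females, 3 given CB-100 and 2 sham. Mitochondrially encoded genes took 26.8% ± 6.44 (SD, n = 4) of the counts in CB-100 and 18.8% ± 4.29 (SD, n = 3) in sham, a difference of 8.02 percentage points that did not pass (exact two-sided permutation p = 0.143; BH-adjusted p = 0.229 over 8 measures). As a share of protein-coding counts it was 11.9 points (exact permutation p = 0.0571, BH-adjusted p = 0.114). The small structural RNAs 7SL and 7SK, of the signal recognition particle and of transcription control, took 11.4% ± 2.10 (SD, n = 4) against 6.99% ± 1.25 (SD, n = 3), and each CB-100 library lay above each sham library. Protein-coding genes held 78.5% ± 1.76 (SD, n = 4) against 84.9% ± 1.78 (SD, n = 3), again without overlap. For both measures the exact permutation p was 0.0286, the smallest that 35 splits can give, and it became 0.114 after BH adjustment. The first principal component held 37.3% of the variance and put the 4 CB-100 libraries on one side and the 3 sham libraries on the other.

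**Figure D1:**
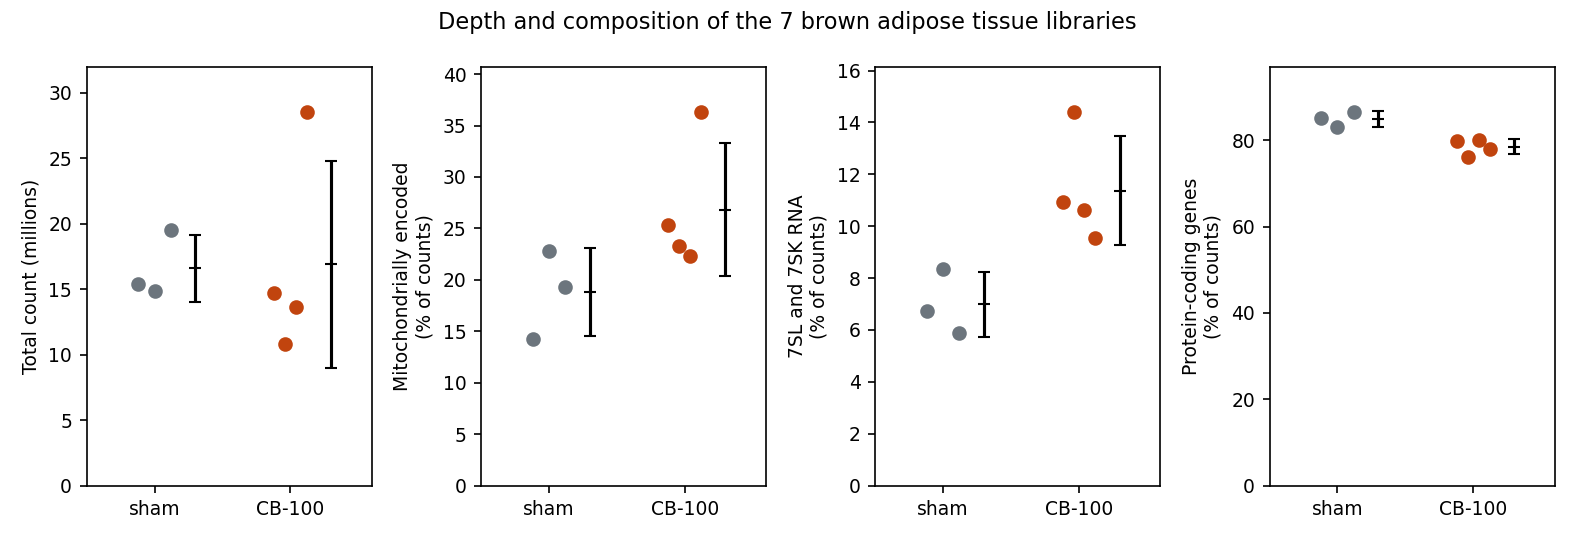
Total count and the percent of counts in mitochondrially encoded genes, in 7SL and 7SK RNA and in protein-coding genes, with a point per library (3 sham, 4 CB-100) and the mean ± SD as a bar beside them. The CB-100 libraries hold more 7SL and 7SK RNA (11.4% against 6.99% on average) and a smaller protein-coding share (78.5% against 84.9%).

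Brown fat of CB-100 mice held 21.4-fold more Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, and 6.06-fold less Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, whose gene has an overlapping model on the opposite strand. Scd1 stood at 4620 ± 1904 CPM (SD, n = 4) in CB-100 and 216 ± 146 CPM (SD, n = 3) in sham, and Pck2 at 16.3 ± 3.26 against 98.3 ± 26.4 CPM. Of 16823 genes tested, 622 (3.70%) passed edgeR's quasi-likelihood test at a BH-adjusted p of 0.05, 239 higher and 383 lower in CB-100. Of the called genes, 139 were at least 2-fold higher and 206 at least 2-fold lower, and 525 were protein-coding. Each of the 622 kept the 4 CB-100 libraries apart from the 3 sham libraries, which 23.3% of tested genes did and which chance gives for 5.71%. The number of called genes rests on the library set. It was 97 without CB-100 replicate 1, 24 without CB-100 replicate 2, 187 without CB-100 replicate 3, 14 without sham replicate 1, 319 without sham replicate 2 and 8 without sham replicate 3, against 610 without CB-100 replicate 4. In the 5 females alone edgeR called 0 genes (2578 at an unadjusted p under 0.05), and it called 9 against a fold change of 1.5, 10 with a skeletal muscle score as covariate and 238 with sex as covariate, while DESeq2 called 1826 and limma voom 1150.

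Among the protein-coding genes with the largest called increases, Scd1 (log2 change 4.42, SE 0.70, edgeR adjusted p = 0.026) came first. It lies at chromosome 19, 44394455 to 44407879, on the minus strand of GRCm38, and its count is uncertain, being non-whole in each of the 7 libraries and of a gene family. Scd1 did not stay called without CB-100 replicate 1, CB-100 replicate 2 or any 1 of the 3 sham libraries, with log2 changes of 3.95 to 4.88 and an edgeR adjusted p of up to 0.091. Akap5, an anchoring protein for protein kinase A, rose 6.25-fold, from 2.23 ± 0.22 to 14.0 ± 4.29 CPM (edgeR adjusted p = 0.011). Gk, the glycerol kinase that recycles glycerol into triglyceride, rose by 2.59 on the log2 scale (SE 0.56, edgeR adjusted p = 0.049). S100b, a calcium-binding protein of Schwann cells and adipocytes, rose by 2.51. Agpat2, an acyltransferase of triglyceride synthesis, rose by 2.20, and since Egfl7 overlaps it on the opposite strand its count is uncertain. Oas2, an interferon-induced oligoadenylate synthetase, rose by 2.19, and Cpn2, a subunit of carboxypeptidase N, by 2.08. Others were Gm44502 (log2 change 3.45, overlapping Chkb and Cpt1b and thus uncertain), the ferlin gene Fer1l6 (2.71), BC034090 (2.31, uncertain for an opposite gene model) and Lrp11 (2.13).

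The 12 largest called decreases held 3 genes with the smallest adjusted p of the comparison (edgeR adjusted p = 0.0051 for each). These were Aldoc, the aldolase C of glycolysis (log2 change -2.67, SE 0.24), Pck2 (-2.60, SE 0.22) and Ripk4, a receptor-interacting kinase (-2.60, SE 0.23). Aldoc lies at chromosome 11, 78322968 to 78327781, Pck2 at chromosome 14, 55540266 to 55551242, and Ripk4 at chromosome 16, 97741933 to 97763787. Aldoc stood at 1.70 ± 0.40 CPM (SD, n = 4) in CB-100 against 10.8 ± 1.45 CPM (SD, n = 3) in sham. Cyp2b10, a cytochrome P450 of xenobiotic metabolism, fell from 107 ± 77.7 to 7.90 ± 4.47 CPM (log2 change -3.75, edgeR adjusted p = 0.034). Zim1, an imprinted zinc finger gene, fell by 3.43 on the log2 scale, Cxcl13, a chemokine that attracts B cells, by 3.22. Mycl, a MYC family factor, fell from 36.9 ± 25.2 to 4.73 ± 3.35 CPM. Fkbp5, a co-chaperone of the glucocorticoid receptor whose transcription glucocorticoids raise, fell by 2.59 (SE 0.49, edgeR adjusted p = 0.037), with 57.0 ± 48.7 CPM in sham and 9.50 ± 1.70 CPM in CB-100, and by 1.61 without sham replicate 1. Wfikkn2, a secreted protease inhibitor that binds myostatin, fell by 2.88, the kinesin Kif27 by 2.60 and the copine Cpne9 by 2.80, the last with a log2 change of -1.83 without sham replicate 3 (edgeR adjusted p = 0.11). Gm9747 fell by 3.69 and lies opposite Irs1, so that its count is uncertain. Counts are uncertain for the same reason in Gk, Kif27, Cpne9 and Pck2, each overlapped by another gene model. The 23 leading genes given here kept their direction without each library in turn, which their lack of overlap between the groups gives beforehand. Of them 4, 6, 8 and 14 stayed called without CB-100 replicates 1, 2, 3 and 4, and 4, 17 and 3 without sham replicates 1, 2 and 3. Aldoc, Pck2 and Ripk4 stayed called without any single library, and in the 5 females alone their edgeR adjusted p was 0.056, 0.056 and 0.067.

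**Figure D2:**
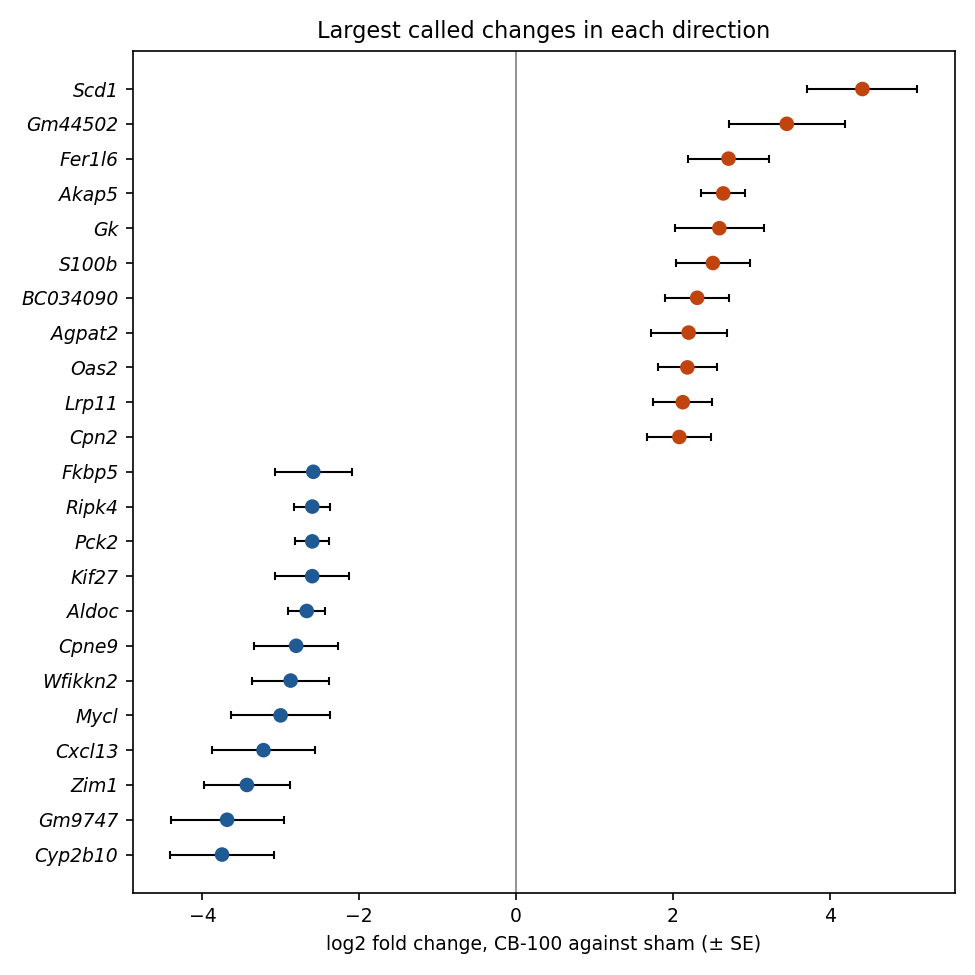
Log2 fold change of CB-100 against sham with its standard error for 11 protein-coding genes with the largest called increases and the 12 with the largest called decreases (4 CB-100 and 3 sham libraries). Scd1 leads the increases at 4.42 and Cyp2b10 the decreases at -3.75.

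Genes chosen before the data were examined as markers of the tissue did not pass the test. Ucp1, the uncoupling protein of brown fat heat production, stood at 1402 ± 791 CPM (SD, n = 4) in CB-100 and 354 ± 454 CPM (SD, n = 3) in sham (log2 change 1.99, SE 0.98, edgeR adjusted p = 0.26). Without sham replicate 2 its log2 change was 3.92 (edgeR adjusted p = 0.058). Adipoq, which encodes adiponectin, stood at 366 ± 7.28 CPM in CB-100 and 690 ± 179 CPM in sham (log2 change -0.91, SE 0.21, edgeR adjusted p = 0.051), just outside the threshold. Lep, which encodes leptin, gave a log2 change of 1.66 (SE 1.02, edgeR adjusted p = 0.35). Ins2, an insulin gene, did not pass the filter on low counts.

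**Figure D3:**
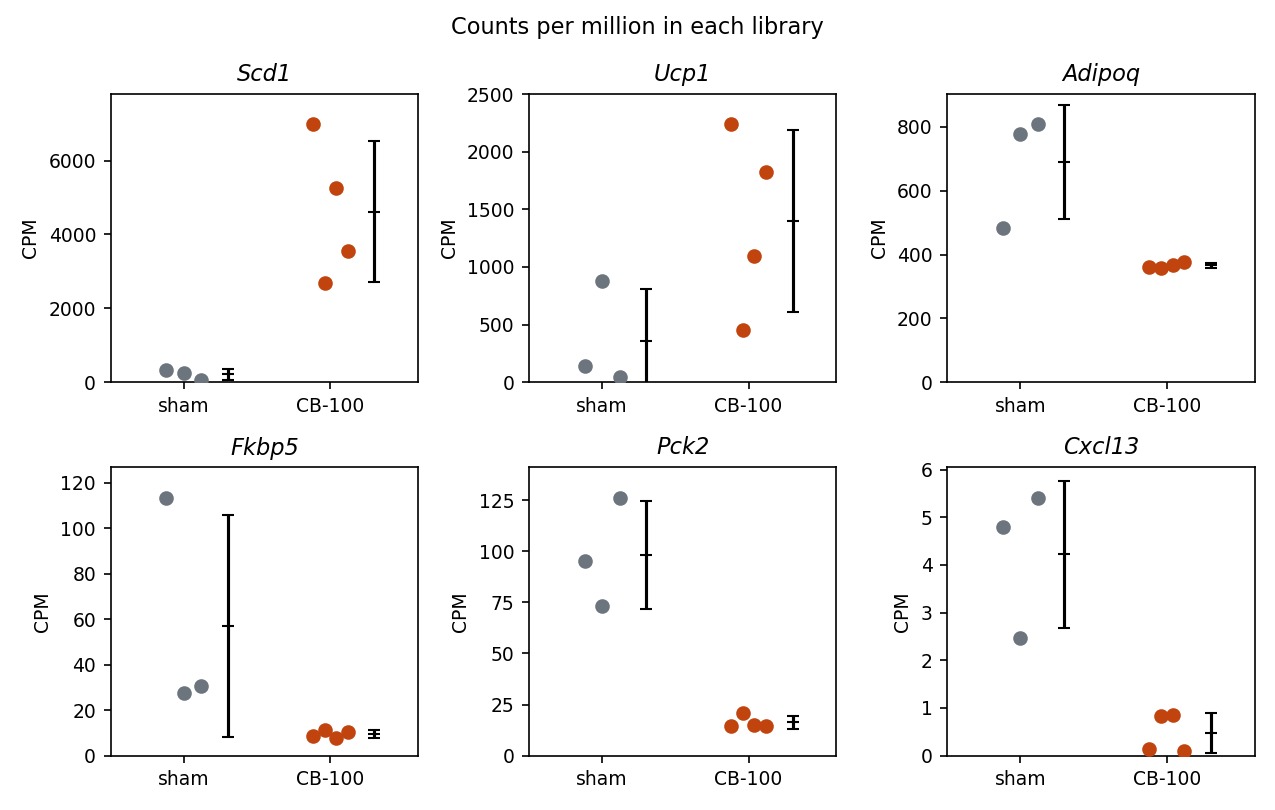
Normalized CPM in each library for Scd1, Ucp1, Adipoq, Fkbp5, Pck2 and Cxcl13, with the mean ± SD as a bar beside the points (3 sham, 4 CB-100), each panel on its own linear axis from 0. Scd1, Pck2, Fkbp5 and Cxcl13 separate the groups without overlap, Ucp1 does not, and Adipoq does but missed the threshold (edgeR adjusted p = 0.051); the lower bar of Ucp1 in sham is cut at 0.

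Genes of fatty acid and triglyceride synthesis rose as a group. Of 24 tested members, 6 rose, 0 fell and 18 did not pass (11 higher and 1 lower adjusted over the list alone), with a median log2 change of 0.44. Besides Scd1 and Agpat2, Pnpla3, a lipid droplet acyl hydrolase, rose by 1.90 (SE 0.40) and Scd2 by 1.76 (SE 0.34), both uncertain for an overlapping gene and non-whole counts. Camera with a preset correlation placed the list up (adjusted p = 5.3e-05), against an adjusted p = 0.23 with an estimated correlation. Cholesterol synthesis genes had a median log2 change of 0.49 (camera adjusted p = 0.010, but adjusted p = 0.55 with an estimated correlation), yet their called members went both ways, 2 higher and 2 lower of 21 (6 and 2 adjusted over the list alone). Idi1, an isomerase of the pathway, rose by 0.64, while Fdft1, the squalene synthase, fell by 2.19 and Acat2, an acetyl-CoA acetyltransferase, by 0.85. Fdft1 overlaps Ctsb on the opposite strand and Idi1 an opposite gene model, and these 2 and Acat2 have non-whole counts and are uncertain.

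Genes induced by fasting or low insulin, some of which glucocorticoids also raise, such as Fkbp5, mostly had estimates below 0. Of 23 tested members, 4 fell and 0 rose (10 and 0 adjusted over the list alone), 21 estimates were below 0 and the median log2 change was -0.87 (camera adjusted p = 1.7e-08, against an adjusted p = 0.22 with an estimated correlation). Fkbp5 led, followed by Txnip, an inhibitor of glucose uptake (fell by 1.40, SE 0.26), Bnip3, a mitophagy receptor (fell by 1.34, SE 0.24), and Mt1, a metallothionein (fell by 0.92, SE 0.16). The median was -0.53 without sham replicate 1. Txnip and Bnip3 have overlapping opposite gene models and non-whole counts, and are uncertain. In the insulin signalling list no member of 24 passed, in the main test or adjusted over the list alone (median log2 change -0.04, camera adjusted p = 0.73). Its members with the smallest p were Foxo3 (log2 change -0.86) and Trib3 (-0.75).

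Nuclear genes of mitochondrial respiration were lower in CB-100, and genes on the mitochondrial genome were not. Of 28 nuclear-encoded respiratory chain genes, 9 fell and 0 rose (27 and 0 adjusted over the list alone), with each estimate below 0 and a median log2 change of -0.84 (camera adjusted p = 9.8e-20, but adjusted p = 0.40 with an estimated correlation). Ndufa4, linked to complex IV, fell from 234 ± 34.4 to 89.5 ± 31.5 CPM (log2 change -1.38, SE 0.30, edgeR adjusted p = 0.043). Sdhb, of succinate dehydrogenase, fell by 1.15, Ndufb3, of complex I, by 1.11 and Cox7b, of cytochrome c oxidase, by 1.10. Of the 13 mitochondrially encoded subunits 0 passed in edgeR's test (nor adjusted over the list alone) and 12 estimates were above 0. Their median log2 change was 0.95 (camera adjusted p = 8.2e-05, but adjusted p = 0.57 with an estimated correlation). mt-Nd3 gave 1.78 (SE 0.62, uncertain for non-whole counts) and mt-Cytb 1.48 (SE 0.55). As given above, the difference in the share of mitochondrially encoded counts did not pass. Without CB-100 replicate 4 that difference was 4.86 percentage points in place of 8.02, and the list's median was 0.56.

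Genes of fuel oxidation followed the nuclear respiratory chain. In fatty acid oxidation 3 of 24 genes fell (4 adjusted over the list alone) and 0 rose, with a median of -0.56 (camera adjusted p = 5.1e-07, against an adjusted p = 0.57 with an estimated correlation). Etfa and Etfb, the electron transfer flavoprotein subunits, fell by 1.36 and 1.17, and Eci1, an enoyl-CoA isomerase, by 1.26. Etfb is overlapped by another gene model, both Etfb and Eci1 have non-whole counts, and both are uncertain. In the citric acid cycle list 1 of 24 fell, Sdhb (8 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 3.1e-07, against an adjusted p = 0.57 with an estimated correlation). In glucose uptake and glycolysis 2 of 21 fell, Aldoc and the glucose phosphate isomerase Gpi1 (fell by 1.10, uncertain for an opposite gene model and non-whole counts), and 2 did so adjusted over the list alone. The median was -0.28 (camera adjusted p = 0.044, against an adjusted p = 0.69 with an estimated correlation). This call was lost without CB-100 replicate 1 (median -0.31), CB-100 replicate 2 (-0.14) or sham replicate 2 (-0.12, camera adjusted p = 0.39), and with sex or a skeletal muscle score as covariate. Without sham replicate 1 the median was -0.43.

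The brown adipocyte list itself did not move together. Of 24 thermogenesis and brown adipocyte identity genes 1 rose, Gk, and 1 fell, Slc27a2, a fatty acid transporter uncertain for an opposite gene model (log2 change -1.26, SE 0.24), against 2 and 1 adjusted over the list alone. The median was 0.15 and the mean 0.55 (camera adjusted p = 0.41), with a median of 0.086 without sham replicate 3 and 0.065 with the length and GC correction. Lipolysis, lipid uptake and lipid droplet genes had a median of -0.15 (camera adjusted p = 0.47), with no call among 22, adjusted over all genes or over the list alone. Pnpla2, the adipose triglyceride lipase, stood at 1645 ± 421 CPM in CB-100 and 3287 ± 255 CPM in sham (edgeR adjusted p = 0.075) and Lipe, the hormone-sensitive lipase, gave a log2 change of -0.66 (edgeR adjusted p = 0.13, uncertain for an opposite gene model and non-whole counts). Among adipokines and secreted factors Nampt, an NAD synthesis enzyme, fell by 1.13 as the 1 call of 19 (2 higher and 3 lower adjusted over the list alone), and the list's median was 0.41 (camera adjusted p = 0.19), against 0.66 without sham replicate 2, where it passed (camera adjusted p = 0.012). White adipocyte markers gave 0.27 (camera adjusted p = 0.71, 0 of 11 called, 1 lower adjusted over the list alone; 0.084 without sham replicate 1 and 0.56 without sham replicate 2), with Agt at -2.33 (edgeR adjusted p = 0.065) and Retn at 0.81. The creatine, calcium and peroxisomal cycling list gave 0.12 (camera adjusted p = 0.93, 0 of 14 called in either count), with Slc6a8, a creatine transporter, at -1.18 and Ryr2, a calcium channel, at 0.78.

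Ribosomal protein and antioxidant genes fell as groups. Of 25 cytosolic ribosomal protein genes 10 fell and 0 rose (22 and 0 adjusted over the list alone), with a median log2 change of -0.55 (camera adjusted p = 3.4e-14, against an adjusted p = 0.22 with an estimated correlation). Rpl8 fell by 1.01 (SE 0.17, edgeR adjusted p = 0.027), and Rpl23, Rps6 and Rpl27, uncertain for non-whole counts, fell by 0.92, 0.85 and 0.83. Random lists of protein-coding genes matched on expression and exon length had a median of -0.31, and 5.44% of them lay as low as this list. Of 20 antioxidant genes 6 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.50 (camera adjusted p = 2.7e-07, against an adjusted p = 0.23 with an estimated correlation). Txn1, a thioredoxin, fell by 1.41 (SE 0.18, edgeR adjusted p = 0.020), Cat, the catalase, by 0.98, Sod1, a superoxide dismutase, by 0.94 and the peroxiredoxin Prdx1 by 0.91. The unfolded protein response list had 1 call of 22, Sdf2l1 (log2 change 1.36), against 3 higher and 2 lower adjusted over the list alone, and a median of -0.07 with a mean of 0.05 (camera adjusted p = 0.97). That median was -0.18 without CB-100 replicate 4 and -0.015 without CB-100 replicate 3.

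Of the lists for matrix and for non-immune cells other than adipocytes, all but skeletal muscle had medians above 0. The Schwann cell and nerve list rose, with 2 of 11 called (8 adjusted over the list alone), each estimate above 0 and a median of 0.80 (camera adjusted p = 2.9e-06, against an adjusted p = 0.12 with an estimated correlation). S100b led it, and Pmp22, a myelin protein, rose by 0.80 (SE 0.17). Extracellular matrix genes had a median of 0.91 with 24 of 25 estimates above 0 (camera adjusted p = 5.1e-08, against an adjusted p = 0.57 with an estimated correlation). None of them passed over all genes, while 14 were higher and 1 lower adjusted over the list alone. Col5a1, a collagen chain, gave 1.55 (SE 0.36, edgeR adjusted p = 0.051, uncertain for opposite gene models), and Dcn, which encodes decorin, -0.74 (SE 0.18, edgeR adjusted p = 0.055). Vascular genes gave a median of 0.35 with 0 of 21 called and 1 higher adjusted over the list alone (camera adjusted p = 0.014, against an adjusted p = 0.76 with an estimated correlation). That call was lost without CB-100 replicate 4, where the median was -0.0026, without sham replicate 3 (median 0.23) and in females alone, and the median was 0.60 without sham replicate 1. Egfl7, an endothelial factor, gave 1.19 and Nos3, the endothelial nitric oxide synthase, 0.75, both uncertain for overlapping genes and Nos3 also for non-whole counts. Preadipocyte and fibroblast markers gave 0.50 (camera adjusted p = 0.097, 0 of 21 called in either count), with Pdgfrb at 0.72 and Thy1 at 1.10. That list passed without CB-100 replicate 1 (0.63, camera adjusted p = 0.029) or sham replicate 2 (0.66, camera adjusted p = 0.0025), and its median was 0.24 without CB-100 replicate 2, 0.26 without CB-100 replicate 4 and 0.28 without sham replicate 3. Lymphatic markers gave 0.28 (camera adjusted p = 0.46, 0 of 8 called in either count; 0.11 without sham replicate 3 and 0.10 in females alone, camera's direction being down in both), with Pdpn at 1.22 and Mmrn1 at -0.62. Skeletal muscle genes, the sign of muscle taken with the fat, were placed lower (median -0.57, 0 of 23 called in either count, camera adjusted p = 0.031), against an adjusted p = 0.80 with an estimated correlation. Actn3 gave -1.19 (SE 0.80) and Mylpf -1.11 (SE 0.64). The muscle call was lost without CB-100 replicates 1, 2 or 4 or sham replicate 2 (medians -0.29, -0.34, -0.32 and -0.26), and the median was -1.71 without CB-100 replicate 3, whose mean over these genes (6.74 log2 CPM) was the highest of the 7 libraries. It was -1.60 in females alone (camera adjusted p = 8.0e-21), -1.06 with sex as covariate (camera adjusted p = 3.4e-04) and -0.85 without sham replicate 1.

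Among immune lists, interferon response genes had 25 of 26 estimates above 0 and a median of 0.61 (camera adjusted p = 3.8e-05, against an adjusted p = 0.57 with an estimated correlation). Oas2 was the 1 called member, and 2 were higher adjusted over the list alone. The median was 0.37 without CB-100 replicate 4 and 0.33 with the muscle score as covariate. Neutrophil markers had a median of -0.91 on 6 genes, with 5 estimates below 0 (camera adjusted p = 0.022, against an adjusted p = 0.35 with an estimated correlation). Elane, an elastase at 1.28 CPM or less on average, was the 1 called member and fell by 3.58 (2 lower adjusted over the list alone). The camera call of the list was lost without CB-100 replicate 3 or sham replicate 1 (camera adjusted p up to 0.067). MHC class II genes gave 0.40 on 10 members (camera adjusted p = 0.038, against an adjusted p = 0.68 with an estimated correlation), with Ciita, their transcriptional coactivator, the 1 called member in either count, higher by 1.54 and uncertain for Dexi on the opposite strand. The median was 0.80 without sham replicate 2. This call was lost without CB-100 replicate 2, CB-100 replicate 3 or sham replicate 1, with sex as covariate and in females alone (camera adjusted p up to 0.13). Lists for T cells (median -0.19, camera adjusted p = 0.97), cytotoxic lymphocytes (1.31, 0.092, on 5 genes), B cells (0.16, 0.45), macrophages (-0.18, 0.21), cytokines and chemokines (0.09, 0.93) and erythroid cells (0.40, 0.67) did not pass, with the camera adjusted p given second, and Cxcl13 was their 1 called gene. In 3 of these lists the result differed between settings. The filter on low counts was rerun where libraries were left out, so a list's tested members could change. Without sham replicates 1, 2 and 3 the filter kept 17231, 17463 and 17363 genes, against 16823 in the main test. B cells passed without sham replicate 1, 2 or 3 (medians 0.86, 0.70 and 0.25, camera adjusted p = 0.029, 0.034 and 0.046) and had a median of 0.019 without CB-100 replicate 4. Macrophages passed as lower without CB-100 replicate 2 (-0.49, camera adjusted p = 0.0040), without sham replicate 3 (-0.33, camera adjusted p = 0.049) and in females alone (-0.29, camera adjusted p = 0.040). Cytotoxic lymphocytes passed without CB-100 replicate 3 (1.55, camera adjusted p = 0.029) and with the length and GC correction (1.31, camera adjusted p = 0.048), and had a median of 0.69 with the muscle score as covariate. Without CB-100 replicate 1, 2 or 4 the cytotoxic list kept fewer than 5 members and was not tested. Adjusted over each list alone, 1 T cell and 1 B cell gene were higher, Cxcl13 was lower and 0 others passed. The mean log2 change was 0.02 in T cells and -0.17 in cytokines and chemokines, opposite in sign to the median, and camera's direction followed the median in the first and the mean in the second. Among their members, Trac gave 2.32 and Cd3e -1.38 (T cell receptor genes), Ctsw 1.40 and Prf1 1.31 (cytotoxic granules), Ighm 1.47 and Igkc 0.85 (immunoglobulins, uncertain as family members). Cd3e and Ctsw are uncertain for opposite genes. Gpnmb gave -1.84 and Lgals3 -1.36 (macrophages). Without sham replicate 1 the log2 change was -0.56 in Lgals3 and -0.70 in Cd3e, without CB-100 replicate 4 it was 0.31 in Igkc, and with the muscle score as covariate 0.69 in Prf1. In red cells Hba-a2 gave 0.45, uncertain for non-whole counts.

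Stress and cycling genes closed the set. Heat shock and immediate early genes had 21 of 22 estimates above 0 and a median of 0.84 (camera adjusted p = 0.0034, against an adjusted p = 0.57 with an estimated correlation), with 0 called in either count. Egr3 gave 4.22 (SE 1.19) and Egr1 1.95 (SE 0.65). The mean log2 CPM of the list was 5.27 and 5.51 in CB-100 replicates 2 and 4, but 4.04 and 4.08 in replicates 1 and 3, no higher than the 3.57 to 4.08 of sham. Without CB-100 replicate 4 the list did not pass (camera adjusted p = 0.072). In the circadian clock list 1 of 19 rose in either count, Arntl, the core clock activator, uncertain for an opposite gene model (log2 change 2.03, SE 0.42, edgeR adjusted p = 0.039), and the median was -0.10 (camera adjusted p = 0.46). It was -0.37 without CB-100 replicate 1, -0.26 without sham replicate 3 and -0.28 in females alone, without passing. Cell cycle genes gave 0.39 (camera adjusted p = 0.67, 0 of 16 called in either count; 0.11 without CB-100 replicate 4, where camera's direction was down), with Pcna at -0.71 and Top2a at 2.05, uncertain for non-whole counts and for an overlapping gene.

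**Figure D4:**
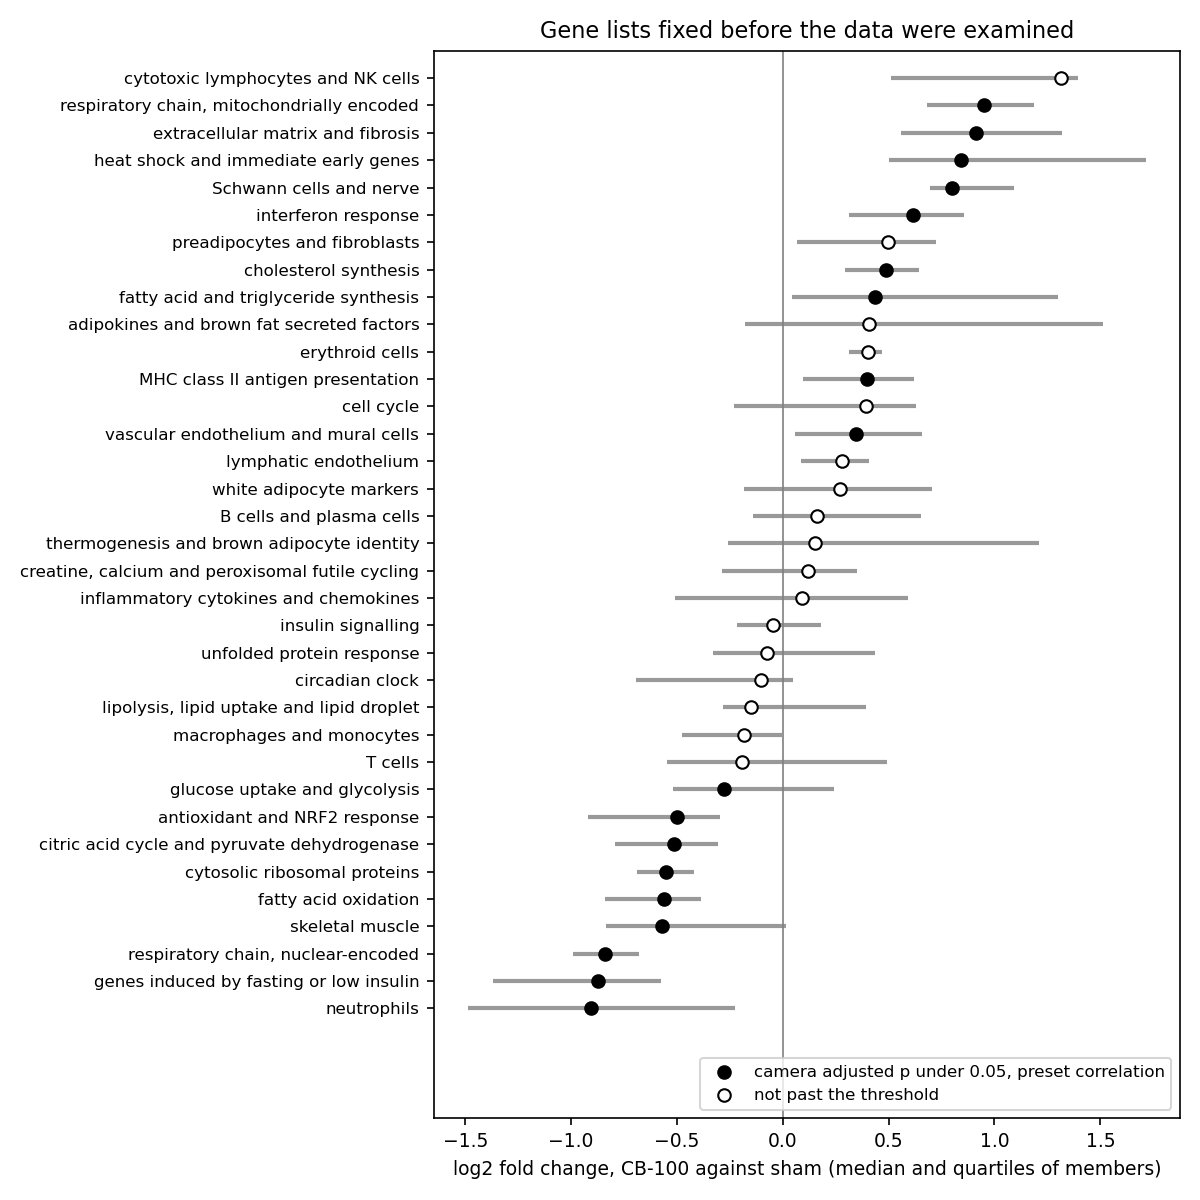
Median (point) and quartiles (line) of the log2 fold change of CB-100 against sham over the tested members of each of 35 gene lists. Filled points mark the 18 lists past a camera adjusted p of 0.05 with a preset correlation, 9 up and 9 down; with an estimated correlation 0 lists passed.

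Across the 35 lists camera with a preset correlation called 18, and with an estimated correlation 0 (5 at an unadjusted p under 0.05, with a smallest adjusted p = 0.12). Fry called 7, the lists for Schwann cells, ribosomal proteins, fatty acid synthesis, fasting-induced genes, antioxidant genes, neutrophils and the nuclear respiratory chain. Exact permutation of each list's mean log2 CPM per library called none of the 35 (smallest BH-adjusted p = 0.125). Its unadjusted p was 0.0286, the smallest that 35 splits can give, for the nuclear respiratory chain and others. That p was 0.114 for matrix, fatty acid oxidation, citric acid cycle and mitochondrially encoded genes, 0.34 for muscle, 0.40 for vascular genes and 0.43 for glycolysis.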

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

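The length and GC test, the brown adipocyte share test and the clock test below were chosen after the results were seen.

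Within the 4 CB-100 libraries, 10 of 132 reported values had 1 library far from the rest, where chance would flag about 1 in 20, or 6.6. CB-100 replicate 3 stood apart in Aldoc (log2 CPM 1.28, the others 0.66 to 0.73), Actn3 (6.55, the others 3.40 to 3.74) and the mean of the creatine, calcium and peroxisomal cycling list (5.34, the others 4.75 to 4.84), which holds the muscle gene Atp2a1. CB-100 replicate 2 stood apart in Pck2 (4.41, the others 3.85 to 3.94), Ighm (3.75, the others 3.02 to 3.10), Mmrn1 (1.21, the others 1.34 to 1.36) and the mean of the T cell list (0.64, the others -0.14 to -0.06). CB-100 replicate 4 stood apart in Pcna (4.02, the others 2.95 to 3.04) and the mean of the erythroid list (5.97, the others 4.19 to 4.47). CB-100 replicate 1 stood apart in Idi1 (4.36, the others 4.19 to 4.22). The sham group of 3 was not tested. A difference of the CB-100 effect between sexes was tested as an interaction, with 1 male per group, and edgeR called 0 genes (283 at an unadjusted p under 0.05).

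The count of 622 called genes was set against the other splits of the 7 libraries into 4 and 3. Of 35 splits, 1, the real one, gave as many genes, and the highest of the others gave 4, which argues against a chance split, 1 of 35 being the smallest share these splits can give. At an unadjusted p under 0.05 the contrast was smaller, with 4022 genes against up to 2820 in another split. Any feature that goes with the groups remains open, such as the injection, the code in the titles or the handling of the samples.

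Nuclear-encoded respiratory chain genes were lower in CB-100, with a median log2 change of -0.84 over 28 genes. Calls went with exon length: of 2669 protein-coding genes in the fifth with the shortest exons 14 rose and 139 fell (median of all -0.12), against 68 and 28 in the longest (median 0.080). After correction for length and GC the list's median was still -0.80, and 0 of 10000 random lists matched on expression and length lay as low. Those random lists had a median of -0.31 themselves, so part of the -0.84 is shared by genes of like expression and length. They do not carry the correlation between the list's genes, estimated at 0.85. The Spearman correlation was -0.19 with expression, 0.15 with length and 0.16 with GC, and no correction for expression was made. Muscle carried over in dissection would leave little change once the muscle score is a covariate, but the median was -0.78. The mean log2 CPM of the muscle list was 3.83, 4.51 and 4.51 in CB-100 replicates 1, 2 and 4, below the 5.16 to 6.18 of sham. Only CB-100 replicate 3 (6.74) thus lets the covariate separate muscle from group. A lower share of brown adipocytes would lower their markers by about as much. That list's median was 0.15 with a lower quartile of -0.26, and 0.065 after the length and GC correction. This test cannot decide the share, since the list's members went both ways, with 14 of 24 estimates above 0. Ucp1 (1.99), Gk (2.59), Prdm16 (0.17) and Ebf2 (0.13) lay above 0 and Slc27a2 (-1.26) below. Outside that list, Adipoq (-0.91) and Lipe (-0.66) were lower without overlap between the groups, while the lipolysis list's median was -0.15. The test also asked that other cell types move apart, a part not used here: matrix (0.91), Schwann cell (0.80), preadipocyte (0.50) and vascular genes (0.35) had medians above 0, the direction a lower share would give, while neutrophils (-0.91, on 6 genes), skeletal muscle (-0.57) and macrophages (-0.18, not passing) lay below 0, with calls or signs that depend on single libraries. These values argue against the length and GC trend as the whole cause. Against carried-over muscle as the whole cause they argue only as far as CB-100 replicate 3 can decide. A lower share of brown adipocytes stays open. A technical difference between the groups, as in RNA quality or batch, was not tested and stays open too. The groups did not overlap in their shares of small structural RNAs and of protein-coding counts, and calls went with exon length. A change within adipocytes with the injection or the title code may remain as a hypothesis beside these.

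Fatty acid synthesis genes were higher and fasting-induced genes lower, with medians of 0.44 and -0.87. After the length and GC correction the medians were 0.39 and -0.83 and Scd1 stayed at 4.42, which argues against that trend. Each group held 1 male, so the sexes were nearly balanced by design and a test of females alone adds little. In females alone the medians differed by 1.47. Time of day cannot be told apart from the group, since no hour of collection is given. Arntl rose while Dbp, Nr1d1, Nr1d2, Tef and Hlf, which peak opposite to it, had a median of -0.10. Tef gave -0.42 (SE 0.25). Of other clock genes, Npas2, Per1 and Cry1 gave 1.99, -0.97 and -0.74 without passing, while Clock and Per3 gave 0.0054 and 0.010. Feeding, insulin status and the injection itself were not tested and may each go with this pattern.

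Some tests were altered once values were known. A test of mitochondrial and 7SL RNA taking counts from other genes had its bounds written beforehand, and its value, a median of -0.84 for the respiratory list with those RNAs left out, met the bound against that explanation. It was set aside after that value was seen, since TMM scaling absorbs a factor common to all other genes and the omission moves almost nothing, and the test on brown adipocyte markers took its place. The bound for the clock genes was tightened by a margin of 1 SE after their values were seen; under the first bound time of day would have been counted as excluded. The test of the sexes was written after the count with sex as covariate was known and before the values in females were.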

How the results depend on the processing

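The length and GC correction, the females-only analysis, the omission of mitochondrial, 7SL and 7SK RNA and the list tests with sex as covariate were chosen after seeing the data; the others were planned. Against 622 genes in the main comparison, DESeq2's Wald test called 1826, limma voom 1150 and a threshold of 0.1 1860. A test against a fold change of 1.5 called 9, the muscle score as covariate 10, sex as covariate 238 and the length and GC correction 398, of which 373 were shared with the 622. In females only edgeR called 0 (2578 at an unadjusted p under 0.05). Leaving out each library gave 8 to 610. Fewer mice and the added covariate leave fewer degrees of freedom; the cause was otherwise not tested. Other scalings, filters and gene sets gave 606 to 914 genes, and the share of lower genes was 53.5% with upper quartile scaling against 61.6%. Of the 622, each gene with a value kept its direction in each alternative. Where libraries were left out, the lack of overlap between the groups in these genes gives this beforehand. The other settings reuse the same 7 libraries. The 18 called lists became 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 7 with fry, and 15 to 19 without each library. The nuclear respiratory chain, fasting-induced, fatty acid synthesis, Schwann cell, antioxidant and ribosomal lists stayed called in each alternative but the estimated correlation.

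Medians of lists that reversed, with their range without each library, were those of cytokines and chemokines (-0.27 without CB-100 replicate 2 to 0.38; -0.034 with the muscle score), creatine cycling (-0.016 without CB-100 replicate 3 to 0.17; -0.089 in females), vascular genes (-0.0026 without CB-100 replicate 4 to 0.60), erythroid genes (-0.32 without CB-100 replicate 4 to 0.94) and T cells (-0.29 to 0.026 without sham replicate 1; 0.084 without mitochondrial, 7SL and 7SK RNA). Without sham replicate 2 so did lipolysis (range -0.26 to 0.10), insulin signalling (-0.062 to 0.011) and macrophages (-0.49 to 0.027). Hba-a2 (-0.21 without CB-100 replicate 4, up to 1.07) reversed as well. Where libraries or genes were left out the low-count filter was rerun, so a median could move because the tested members changed. Without mitochondrial, 7SL and 7SK RNA 17003 genes were tested, against 16823. The cause was otherwise not tested, and of these lists only the vascular one had been called. The shares of counts moved by less than 1 SD in each alternative. Genes under about 1 CPM, such as most lymphocyte markers, rest on few counts.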

Other observations

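The lists below were written after the main results were seen and before their own tests, and leave out genes already seen among the largest changes of each complex.

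Proteasome genes were lower in CB-100: 11 of 30 members fell and 0 rose, each estimate was below 0, and the median log2 change was -0.62 (camera adjusted p = 1.3e-16, against an adjusted p = 0.10 with an estimated correlation). Psmb2 fell by 1.09 and Psmb4 by 1.03. Of 12 genes of the CCT chaperonin and prefoldin, which fold tubulin and actin, 5 fell, led by Cct8 (fell by 0.90) and Cct4 (fell by 0.84), with a median of -0.59 (camera adjusted p = 5.0e-07, against an adjusted p = 0.10 with an estimated correlation). Mitochondrial ribosome genes had a median of -0.39 with 0 of 25 called (camera adjusted p = 5.3e-06, against an adjusted p = 0.25 with an estimated correlation), and cytosolic aminoacyl-tRNA synthetases -0.45 with 2 of 19 lower, Hars and Tars (camera adjusted p = 3.1e-06, against an adjusted p = 0.10 with an estimated correlation). Collagen and matrix-processing genes outside the main matrix list had a median of 0.47 with 2 of 25 higher, Col5a3 (1.93) and Bmp1 (1.26), and camera placed them up (adjusted p = 3.1e-06, against an adjusted p = 0.21 with an estimated correlation).

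A hypothesis was that such complexes are lower in CB-100 by more than their length and expression give. Of random lists matched on both, at most 0.21% lay as low as any of the 4 complex lists, the highest of their 4 percentiles, and after the length and GC correction their medians ran from -0.58 to -0.35. Cytosolic ribosomal proteins, a complex of the main lists and not part of the test, lay at 5.44%, outside the bound of 5% set for the 4. For the 4 lists the percentiles met that bound, on the same 7 libraries in which the hypothesis was formed. Random lists do not carry the correlation between members of a complex. With an estimated correlation the camera adjusted p of the 4 lists was 0.10 to 0.25, so the hypothesis stays open. Its wording was settled after the result, with the lists and the bound left as written before.

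A second hypothesis was that transcripts induced by glucocorticoids are lower in CB-100, after Fkbp5 and Mt1 had been seen. Both are called members of the fasting-induced list, so the lower values of that list are not separate from this hypothesis. In 14 tested genes, all but Mertk (-0.029) outside the main lists, the median log2 change was -0.46, with 10 estimates below 0. Camera gave p = 0.0093, against p = 0.25 with an estimated correlation. Map3k6 was the 1 called member (fell by 1.70), Hif3a gave -1.85 and Zbtb16 -1.48 without passing (edgeR adjusted p = 0.065 and 0.064), and Sgk1 gave 0.85. A lower glucocorticoid signal may account for this, but no hormone was measured, and the result rests on a preset correlation.

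Of 629 processed pseudogenes tested 2 were called higher and 32 lower, and of 1103 unconfirmed transcripts of the TEC class 15 higher and 2 lower; neither class was tested as a set.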
